A study of Mus musculus with 2 samples.

How the data were processed

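RNA was measured in laser-captured areas of liver from PiZ mice, a C57BL/6 strain that carries the human gene and promoter of the Z mutant of alpha-1-antitrypsin (ATZ). The mutant protein polymerises and collects in hepatocytes as globules. Per the labels' protocols and the series' design text, untreated mice on standard chow were killed at 3 months of age. Frozen sections were stained with Cresyl Violet, and areas with and without globules were cut out by laser, so the areas were chosen by morphology. RNA was extracted with a PicoPure kit, and 50 ng per array was amplified and labelled with the NuGEN Ovation WTA System V2. Each of the 2 groups is 1 array, and each array holds RNA pooled from 2 mice. Whether the same mice gave both pools, and how many areas were cut, is not given in the sources used here.

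The deposited table holds log2 values, 1 per probe set, for 72688 probe sets. Per the submitters' processing notes, the Transcriptome Analysis Console was used, with no version named. The background correction, the normalization and the genome build are not given in the sources used here, and no coordinates are printed. The scale was read from the values. They run from 1.85 to 19.93 on the globule-containing and from 1.85 to 19.80 on the globule-free array, and the medians are 4.40 (globule-containing) and 4.49 (globule-free). The highest value of each array was taken as its ceiling, and probe sets within 0.2 of it were taken as saturated. This applies to 21 genes on both arrays, for which no fold is given.

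Genes were named from the platform annotation supplied with the data. Of 32750 probe sets with a listed gene, 30604 named 1 gene and 2146 named several; 39938 probe sets had none listed here. Probe sets that name several genes were left out of the main values, which removed Glul and Serpina1a among others. For 22818 probe sets the Entrez ID matched a RefSeq gene table (GRCm38.p6), which updated 827 symbols. Probe sets of 1 gene were averaged, giving 30142 genes. The members of the mitochondrially encoded list were matched to the table's names for the same genes, such as COX1 and ND2.

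A gene's value is the log2 signal in globule-containing areas minus that in globule-free areas. With 1 array per group there are no residual degrees of freedom, so no test was run and no p-value, SD or standard error of a gene is given. The values describe these 2 arrays, not the spread between mice. Genes were kept where the mean of both arrays was at or above a floor of 4.76, the median over probe sets naming 1 gene, which left 15023 genes. Genes at least 2-fold apart were counted. Background was set after the values were seen, at the 95th percentile of 1719 olfactory and vomeronasal receptor probe sets, at 4.85 (globule-containing) and 5.04 (globule-free). Where 1 array lay at or below this level, or at the ceiling, the fold is given as "at least", with the dim value raised to the background level. Counts of genes at least 2-fold apart use the deposited values, with dim values not raised. Arrays give no read depth, and their number limits the precision.

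The design fixed 35 gene lists before the data were examined, 8 of them as primary. A list's median difference over its members above the floor was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile is given as a description of these arrays. A list with fewer than 5 members above the floor has values only. A list was said to stand apart below the 2.5th or above the 97.5th percentile. On simulated arrays of 15023 genes for this comparison, made by shuffling the differences within bins of expression, 4 of 100 unchanged lists of 20 genes stood apart. With a log2 shift of 0.5 in all members, 98 of 100 did. Shuffling unlinks genes that vary together, so the 4 of 100 holds for unrelated genes only.

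Named genes followed a rule fixed before the data were examined. Symbols of predicted, RIKEN, small RNA, olfactory, vomeronasal and pseudogene entries, and of variable regions of immunoglobulins and T cell receptors, were left out first. Of the other genes above the floor, the 15 with the largest difference in each direction are named. To these come the 4 members with the largest difference in each list, and the Serpina1 family, Hnf4a, Hspa5, Ddit3, Glul, Cyp2e1, Cyp2f2, Alb and Mki67 whatever their values. Genes whose values are given outside this rule are marked as chosen after their values were seen, except the Y-linked genes and Xist of the sex test. Members of near-identical families (Cyp2c, Cyp2a, Cyp4a, Gstm, Gsta, Ces1, Hsd3b, Serpina1, Saa, Mup, Lyz1 and Lyz2) can share hybridisation, and their values are uncertain to that extent. Alternatives were the floor, the scaling of the arrays, the threshold, the choice of probe set, the matching of random lists and the handling of saturated or dim members. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.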

Results

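Gene expression was compared between globule-containing and globule-free areas of PiZ mouse liver, with 1 array of RNA pooled from 2 mice in each group. The comparison addresses how hepatocyte areas that hold ATZ globules differ from areas without them. Across 15023 genes above the floor, the 2 arrays correlated with Pearson's r = 0.964 and Spearman's rho = 0.929, both across genes, which are not independent replicates. No replicates exist, so every difference below is a difference between 2 arrays with no replicate check. For 192 genes with 2 probe sets above the floor, the differences of both probe sets correlated with r = 0.773 and rho = 0.742 across genes, and their median gap was 0.17 on the log2 scale.

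Globule-containing areas had far higher signals for Ly6d, a surface protein of the Ly6 family, and Gpnmb, a glycoprotein of macrophages and lysosomal stress, and far lower signals for Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, and Hal, the histidine-degrading enzyme of periportal hepatocytes. Ly6d (probe set TC1500001718.mm.1) had a log2 signal of 14.37 in globule-containing and 5.77 in globule-free areas, 388-fold higher. Gpnmb (TC0600000577.mm.1) was 277-fold higher, at 13.27 against 5.16. Cyp8b1 (TC0900003276.mm.1) was 77.9-fold lower, at 5.29 against 11.57, and Hal (TC1000001133.mm.1) was 48.9-fold lower, at 6.89 against 12.50. In all, 972 genes (6.47%) were at least 2-fold higher and 790 (5.26%) at least 2-fold lower in globule-containing areas, and 13261 lay within 2-fold. At least 4-fold differences were seen for 213 higher and 198 lower genes. The median difference over all genes above the floor was 0.05. Lower genes outnumbered higher ones after loess correction, with 841 higher and 973 lower, and after quantile normalization, with 867 and 919.

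Among the other named genes with the largest higher signals, Lyz2, the macrophage lysozyme, was 40.5-fold higher, Lilrb4a, an inhibitory leukocyte receptor, 39.1-fold, Ctss, a lysosomal cysteine protease, 33.8-fold, and Atp6v0d2, a subunit of the vacuolar proton pump, 33.8-fold. S100a8, a calcium-binding protein of myeloid cells, was 60.7-fold higher. Serpina7, which encodes thyroxine-binding globulin, was 135-fold higher, Spink1, a secreted trypsin inhibitor, 53.5-fold, Crip1 43.9-fold and Gstm3, a glutathione transferase, 33.2-fold. Sprr1a was at least 50.6-fold higher, Wfdc16 at least 47.1-fold, Anxa2 at least 28.3-fold and Maoa, monoamine oxidase A, at least 22.5-fold, each against a globule-free signal at background.

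Among the other named genes with the largest lower signals, Cyp2c54 was 56.8-fold lower, Cyp2c50 31.2-fold and Cyp2c37 16.7-fold, all cytochrome P450 enzymes of 1 family whose probes can share signal. Slc3a1, an amino acid transport subunit, had a log2 difference of -5.39, and Etnppl, an ethanolamine phosphate lyase, was 30.1-fold and Got1, the cytosolic aspartate aminotransferase, 22.4-fold lower. Slc10a1, the sodium-dependent bile acid importer, was 19.8-fold lower, Apom, an apolipoprotein of high-density lipoprotein, 18.7-fold and Igfals, the acid-labile subunit of the IGF complex, 20.4-fold. Hsd3b2 was 18.5-fold lower, Ces1e 18.3-fold and Gnat1 27.7-fold. Tff3, a trefoil peptide, was at least 26.9-fold lower, since its globule-containing signal lay at background.

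**Figure D1:**
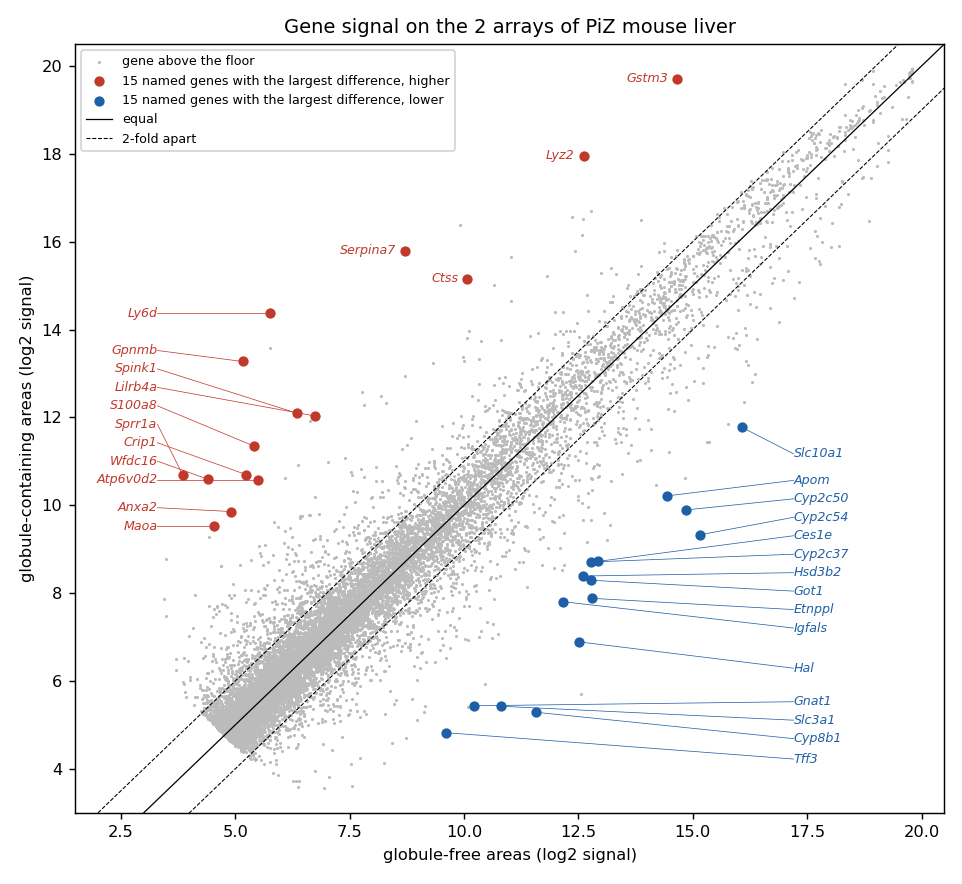
Log2 signal of each gene above the floor on the globule-free array (x axis) and the globule-containing array (y axis), with the 15 named genes with the largest difference in each direction in red (higher) and blue (lower). Most genes lie between the dashed 2-fold lines, and Ly6d, at 14.37 against 5.77, lies farthest above them.

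Genes of periportal hepatocytes were lower as a group in globule-containing areas, on the array where stellate cell genes had a median of 1.75. Cd68 of macrophages was 13.3-fold higher there. The macrophage list had a median of 0.05 but split, with 7 of 19 at least 2-fold higher and 5 at least 2-fold lower. Of 21 measured periportal members, 18 were at least 2-fold lower and none at least 2-fold higher. The periportal median difference was -2.37, below all 10000 matched random lists. Besides Hal and Etnppl, Pigr, the polymeric immunoglobulin receptor, had a log2 difference of -3.91, G6pc, the glucose-6-phosphatase of gluconeogenesis, was 11.7-fold lower and Cyp2f2, a periportal cytochrome P450, 4.96-fold. Alb was at the ceiling on both arrays and gives no fold. Pericentral genes went both ways. Of 20 members, 4 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.40 at percentile 94.8. Gstm3 was 33.2-fold and Aldh3a2, a fatty aldehyde dehydrogenase, 7.99-fold higher, while Cyp2c37 was 16.7-fold and Ces1d 4.85-fold lower. Gstm genes can share hybridisation, and Gstm1 belongs to the list of NRF2 and oxidative stress genes, which was higher. The Gstm3 value therefore cannot be read as lobular position alone. Cyp2e1, a pericentral cytochrome P450, had 18.97 against 18.85. The pericentral median was 0.17, at percentile 46.0, with the floor at the 75th percentile, and 0.50, at percentile 98.2, over members with a mean below 16.

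Chaperones and signalling genes of the endoplasmic reticulum (ER) were higher in globule-containing areas, by modest amounts. Of 27 members, 7 were at least 2-fold higher, 1 at least 2-fold lower and 19 within 2-fold, with a median of 0.50 at percentile 99.7. Atf3, a stress-induced transcription factor, was 4.56-fold higher, Dnajb9, an ER co-chaperone, 3.72-fold and Atf6, an ER stress sensor, 3.27-fold. Asns, the asparagine synthetase induced by amino acid shortage, was at least 4.26-fold higher. Ddit3, which encodes CHOP, was 3.09-fold higher, and Hspa5, which encodes the ER chaperone BiP, 1.59-fold. The list of ER-associated degradation and ER export had a median of 0.49 at percentile 99.5. Of its 25 members, 3 were at least 2-fold higher and none at least 2-fold lower. Derl3, a retrotranslocation channel component, was 5.10-fold higher, Edem2, which trims mannose from misfolded glycoproteins, 4.44-fold and Ubxn4 2.57-fold. Without Derl3 the median was 0.40 and the list no longer stood apart, at percentile 97.4.

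Proteasome subunits were higher nearly throughout: 28 of 29 had a positive difference and 8 were at least 2-fold higher, with a median of 0.80 above all 10000 random lists. Psma5 was 3.27-fold higher, Psmd8 3.10-fold and Psmd14 2.76-fold. The list of autophagy and lysosome genes did not stand apart, with a median of 0.19 at percentile 77.0 over 25 members. Within it, Sqstm1, the autophagy receptor p62, was 5.39-fold higher, Hexa, a lysosomal hexosaminidase, 3.35-fold and Ctsl, cathepsin L, 2.85-fold, while Atg3, which conjugates LC3 to lipid, was 3.56-fold lower. Cytosolic heat shock genes did not stand apart either, with a median of 0.22 at percentile 70.2, and Cryab was the only 1 of 16 at least 2-fold apart, at 2.17-fold higher.

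Antioxidant and detoxification genes regulated by NRF2 were higher. Of 22 members, 12 were at least 2-fold higher and none at least 2-fold lower, with a median of 1.19 above all 10000 random lists. The 12 include Abcc4, chosen after its value was seen. Its fold is only at least 1.43, against a globule-free signal at background. Srxn1, sulfiredoxin, was 27.9-fold higher, Slc7a11, the cystine importer, at least 18.9-fold, Nqo1, a quinone reductase, at least 7.63-fold and Cbr3, a carbonyl reductase, had 7.26 against 5.26. On this array stellate cell genes had a median of 1.75 and Cd68 was 13.3-fold higher, while the endothelial list did not stand apart. The macrophage list did not stand apart by its median of 0.05, but its mean of 0.47 did, at percentile 97.6. Its members split, with 7 of 19 at least 2-fold higher and 5 at least 2-fold lower. Second lists had medians of 1.64 for lipid-associated macrophage genes and 0.09 for resident Kupffer genes. All this holds beside the ER, proteasome and inflammatory lists too.

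Lists of secreted proteins, bile acid genes and hepatocyte transcription factors were lower, on the array where stellate cell genes had a median of 1.75. Cd68 was 13.3-fold higher there. The macrophage list had a median of 0.05 but split, with 7 of 19 at least 2-fold higher and 5 at least 2-fold lower. For complement and coagulation, 14 of 26 members were at least 2-fold lower, with a median of -1.19 below all 10000 random lists. F11, coagulation factor XI, was 8.30-fold lower, C8a 8.06-fold and C8b 5.07-fold, both chains of complement C8. For bile acid synthesis and transport, 10 of 20 were at least 2-fold lower, with a median of -1.13 below all random lists, and besides Cyp8b1 and Slc10a1 the bile acid coenzyme A ligase Slc27a5 was 6.81-fold lower. Other secreted proteins had a median of -0.39 at percentile 0.055, with 3 of 23 at least 2-fold lower. Itih1 was 4.88-fold and Serpinf2 4.61-fold lower, and 4 members were at the ceiling on both arrays. The median of secreted proteins was -0.67 after loess correction and -0.80 over members with a mean below 16. Among hepatocyte transcription factors the median was -0.48 at percentile 0.10. Onecut1, which encodes HNF6, was 4.57-fold lower, Ppargc1a, a coactivator in this list, 4.11-fold and Hnf4a 1.68-fold, whereas Gata6 was 2.29-fold higher. Which cells carry Gata6 in these areas was not measured.

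Metabolic lists were lower by smaller amounts, on the same array with higher stellate cell genes (median 1.75) and Cd68 (13.3-fold). The macrophage list did not stand apart by its median of 0.05, but its members split in both directions. The nuclear-encoded genes of oxidative phosphorylation had a median of -0.49 at percentile 0.010. Of these 28 genes, 26 had a negative difference, and none was at least 2-fold apart. Cholesterol and fatty acid synthesis had a median of -0.41 at percentile 0.030. Of its 24 genes, 7 were at least 2-fold lower, among them Thrsp, a lipogenic regulator, at 8.61-fold and Insig1, a sterol sensor, at 5.16-fold. Gpam, Acly, Scd1 and Fasn of lipid synthesis were also among them. Enzymes of cholesterol synthesis, chosen after their values were seen, went both ways. Hmgcs1 differed by 0.55, Cyp51 by 0.04, Fdps by -0.07 and Sc5d by -0.72. Of these enzymes only Pmvk, at -1.16, was at least 2-fold lower. Fatty acid oxidation had a median of -0.36 at percentile 0.22. Ppara, the nuclear receptor that drives it, was 2.80-fold lower and Pdk4, the pyruvate dehydrogenase kinase, 9.86-fold higher. With the mean in place of the median, this list no longer stood apart, at percentile 9.29.

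The acute phase list was lower, with a median of -0.56 below all 10000 random lists, although its members went both ways. Of 25, 6 were at least 2-fold lower and 3 at least 2-fold higher. Saa4, a constitutive serum amyloid A, was 15.1-fold lower and Itih3 5.38-fold lower, while Lcn2, lipocalin 2, was 16.5-fold higher and Il1rn, the interleukin-1 receptor antagonist, 4.89-fold. The list of NF-kB and inflammatory mediators was higher, with a median of 0.33 at percentile 98.0, 8 of 19 members at least 2-fold higher and 2 at least 2-fold lower. Cxcl9, a T cell chemokine, was 4.57-fold and Cxcl2, a neutrophil chemokine, 2.70-fold higher, whereas Cxcl1 was 3.05-fold lower. This list no longer stood apart after quantile normalization, with a median of 0.23 at percentile 96.8, or without Cxcl9, with a median of 0.29 at percentile 96.9. Interferon response genes did not stand apart, with a median of -0.01 at percentile 31.8. Rtp4 was 3.84-fold higher and Irgm2 3.15-fold lower.

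The cell cycle list did not stand apart, with a median of -0.15 at percentile 6.52 over 19 members, and 17 members lay within 2-fold. Mki67 had 7.02 against 6.76. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 6.52-fold higher and Mcm6, a replication helicase subunit, 2.17-fold lower. The list stood apart as lower after quantile normalization, with a median of -0.24 at percentile 2.36. Apoptosis and p53 target genes had a median of 0.29 at percentile 97.1. Casp12, an ER-associated caspase, was 10.5-fold higher, Trp53inp1 3.16-fold and Ccng1 2.14-fold. This list stood apart after loess correction, with a median of 0.31 at percentile 98.5, with no floor, at percentile 99.6, and by its mean of 0.63, at percentile 99.6. With the floor at the 75th percentile its median was 0.50 at percentile 93.7. Genes of fetal liver and progenitors had a median of 0.54 at percentile 99.3 over 9 members, 7 higher and 2 lower. Afp, chosen after its value was seen, differed by -0.17. Igf2, Dlk1 and Gpc3, also chosen after their values were seen, lay at background on both arrays. With no floor the median was 0.29, at percentile 98.75, and the mean of the list was 1.26, at percentile 99.97. Besides Ly6d, Vim, which encodes vimentin, was 9.82-fold and Cd24a 4.87-fold higher, while Tff3 was lower. Vim is also expressed by stellate cells, fibroblasts and macrophages, and the stellate cell list had a median of 1.75. With differences against background at their bound, a setting chosen after seeing the data, the median of the fetal list was 0.35 and it no longer stood apart, at percentile 95.7.

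The mouse Serpina1 genes, the endogenous relatives of the transgene, had lower signals in globule-containing areas. On that array stellate cell genes had a median of 1.75 and Cd68 was 13.3-fold higher, while the macrophage list split in both directions, with a median of 0.05. Serpina1d was 4.56-fold lower, Serpina1c 2.61-fold, Serpina1b 2.40-fold and Serpina1e 2.12-fold, and Serpina1f lay below background on both arrays. These paralogs are near-identical, so the values cannot be assigned to single genes, and whether the human transgene RNA binds their probes was not tested. No probe set of the human transgene was analysed here.

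**Figure D2:**
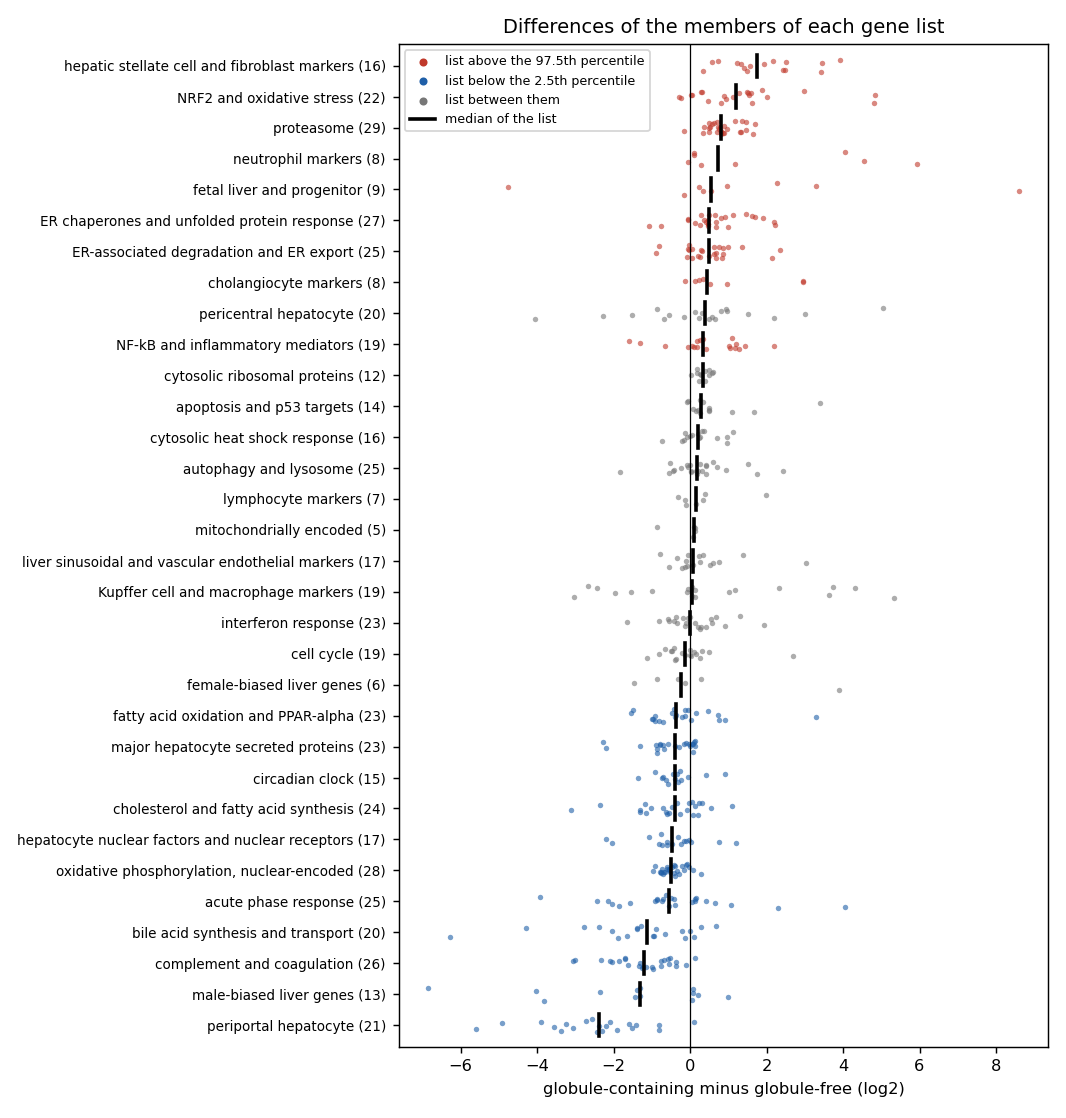
Difference of each list member above the floor between globule-containing and globule-free areas (x axis, log2), 1 line per gene list with at least 5 such members and their number in brackets; black bars are medians. Medians run from -2.37 for periportal hepatocyte genes to 1.75 for stellate cell and fibroblast genes.

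Markers of other liver cell types differed in direction and size. For stellate cells and fibroblasts, 13 of 16 genes were at least 2-fold higher in globule-containing areas, with a median of 1.75 above all 10000 random lists. Lum, lumican, was 15.2-fold higher, Dcn, decorin, 10.7-fold, and Lrat, the retinol-esterifying enzyme of stellate cells, had a log2 difference of 3.46. Endothelial markers did not stand apart, with a median of 0.08 at percentile 50.1, although Rspo3, a Wnt-enhancing ligand, was 8.24-fold higher. Which cells carry Rspo3 was not measured. Macrophage markers had a median of 0.05 at percentile 41.6 and split: 7 of 19 were at least 2-fold higher and 5 at least 2-fold lower. The mean of this list was 0.47, at percentile 97.6. Lyz2, Lyz1 at 19.8-fold, Cd68 at 13.3-fold and Tyrobp at 12.4-fold were higher. Of the markers of resident Kupffer cells, 5 chosen after their values were seen were lower, with a log2 difference of -3.05 for Clec4f, -2.68 for Cd5l, -2.44 for Vsig4, -1.98 for Timd4 and -1.54 for Marco. Adgre1, C1qa and C1qb, also chosen after their values were seen, differed by 0.12, 0.05 and 0.04, and a second list of 12 resident Kupffer genes had a median of 0.09, with 7 above and 5 below 0.

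Neutrophil markers had a median of 0.72 at percentile 99.8 over 8 members. S100a8 at 60.7-fold, S100a9 at 23.2-fold, Lcn2 and Il1b at 2.25-fold were higher, while the granulocyte markers Ly6g, Csf3r and Cxcr2, chosen after their values were seen, differed by 0.27, 0.09 and 0.11. Without S100a8 the median was 0.27, and with no floor it was 0.10 at percentile 94.9, and the list stood apart in neither. Cholangiocyte markers had a median of 0.43 at percentile 98.5. Anxa4 was 7.80-fold higher. Tspan8 was at least 6.52-fold higher and Krt19, chosen after its value was seen, at least 1.05-fold, both against a globule-free signal at background. The cholangiocyte list no longer stood apart with differences against background at their bound, with a median of 0.21 at percentile 95.4, without the member with the largest difference, with a median of 0.34 at percentile 95.9, or against unmatched random lists, at percentile 96.4. Lymphocyte markers had a median of 0.16 at percentile 77.0, with Ptprc, the pan-leukocyte marker CD45, 3.95-fold higher. With no floor the lymphocyte median was -0.13 at percentile 20.34, and the list stood apart in neither. The keratins Krt8 and Krt18, which hepatocytes also express, were 20.4-fold and 6.17-fold higher. The median of 1.54 over 4 members of the mesothelial list rests on these keratins, since the other members above the floor, Upk1b and Gpm6a, had globule-free signals at background. Of the 3 blood cell markers above the floor, with a median of -0.32, none was 2-fold apart.

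**Figure D3:**
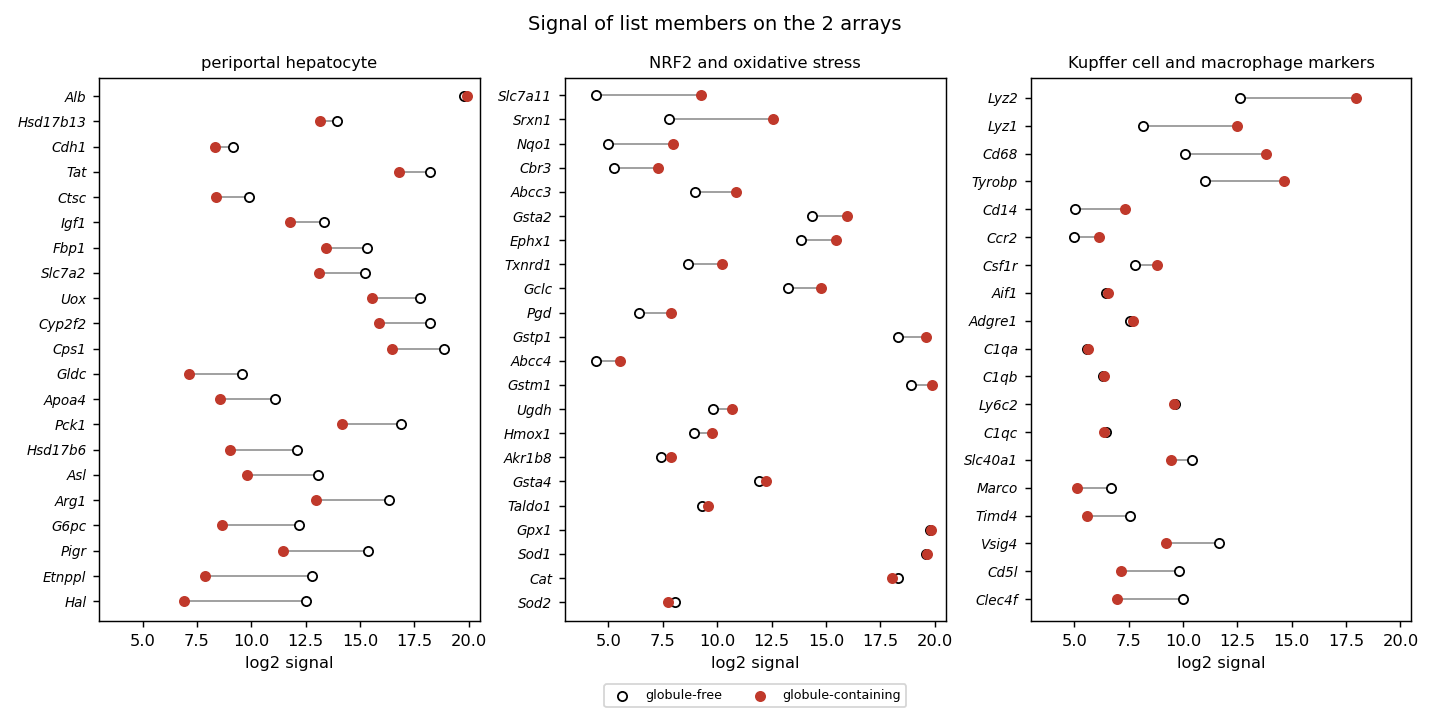
Log2 signal (x axis) of the members above the floor of 3 gene lists in globule-free (open) and globule-containing areas (filled), 1 gene per line. Of 21 periportal genes, 20 have the filled point to the left, most NRF2 genes have it to the right, and macrophage genes split.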

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

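Transcript clusters with no gene listed in the annotation also carried signal, although they entered no comparison. Of 39938 probe sets with no gene listed, 33206 are such clusters and 6732 have control or other identifiers, which were not used here. Of the clusters, 10460 lay above the floor. Of these, 929 were at least 2-fold higher and 808 at least 2-fold lower in globule-containing areas, which is why they are listed here. Among the 2146 clusters that name several genes, 66 were at least 2-fold higher and 40 at least 2-fold lower.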

How the results depend on the processing

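No alternative could use replicates, since leaving out an array leaves no comparison, and precision is limited by 1 array per group. No paired analysis was possible because each group has a single array. The count of higher genes was 642 with the floor at the 75th percentile. With a 1.5-fold threshold 2406 genes were higher and 1786 lower, and with a 3-fold threshold 394 and 347. The other 17 counts stayed within 1.5 times of 972 or 790. The 3 scalings (median centring, quantile, loess) shifted the median of all genes by at most 0.05, and no named gene reversed or moved beyond the spread of genes at its level under them or under the choice of probe set. After loess correction the periportal median was -2.63, the acute phase median -0.82 and the pericentral median 0.23. Chosen after seeing the data, a limit to members with a mean below 16 gave -2.64 for periportal, 0.65 for ER chaperones and 0.50 for pericentral genes, which then stood apart at percentile 98.2. The mean of the ER chaperone list was 0.70. The median of ER-associated degradation was 0.40 without Derl3. The pericentral median was 0.17 with the higher floor. It was 0.40 both against unmatched random lists, at percentile 99.5, and with probe sets of several genes kept, also chosen after seeing the data, at percentile 97.6, and stood apart in both. The NF-kB median was 1.03 with the higher floor, 0.23 after quantile normalization and 0.29 without its largest member, and the cell cycle median was -0.24 after quantile normalization. The other 80 values of primary lists kept their side of the percentile limits. The cause of these shifts was not tested. Of 32 lists with a percentile, 9 stood apart as higher and 11 as lower. The 1.6 expected by chance would hold for lists of unrelated genes. Genes of 1 list can vary together and some lists share members, so this comparison does not exclude chance. Spiked bacterial hybridisation controls were lower on the globule-containing array, with differences of -0.77 for bioB, -0.73 for bioC, -0.44 for bioD and -0.33 for cre, so absolute RNA levels of the areas stay unknown.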

Other observations

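Male-biased genes of mouse liver were lower in the globule-containing areas, on the array where stellate cell genes had a median of 1.75. Cd68 was 13.3-fold higher there, and the macrophage list split in both directions, with a median of 0.05. Of 13 male-biased genes, 8 were at least 2-fold lower, with a median of -1.31 below all 10000 random lists, and -2.36 over members with a mean below 16. Serpina4-ps1 was 116-fold lower, Elovl3, a fatty acid elongase, at least 14.7-fold and Hsd3b5, a steroid dehydrogenase, 14.2-fold. The female-biased list did not stand apart, with a median of -0.23 at percentile 10.2 and a mean of 0.23 at percentile 67.05 over 6 genes. Within it, Cyp2a4, a steroid hydroxylase, was 14.9-fold higher and Cyp2b9 2.78-fold lower. Circadian clock genes had a median of -0.40 at percentile 0.245 over 15 genes. Dbp, an output gene of the clock, was 2.59-fold lower, and 14 genes lay within 2-fold. Cytosolic ribosomal protein genes had a median of 0.33 at percentile 86.1, and all 12 had a positive difference in the values as deposited. Mitochondrially encoded genes did not stand apart, at percentile 31.5, but 3 of 5 were at the ceiling.

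Both tests of the periportal pattern and the test of stellate against endothelial markers were chosen after the list medians they use had been seen. The sex test and the tests on second lists were written before their results were seen, except that Plin2, Hmox1 and Cd163, members of second lists, are also in fixed lists examined earlier, and that the requirement of a lower resident Kupffer list was added after its result. Intervals come from resampling list members, which are not replicates.

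The lower periportal list could reflect fewer hepatocytes in the globule-containing capture. Other hepatocyte products with a mean below 16, which that explanation needs to be lower by as much, had a median of -0.87 over 29 genes against -2.64 over 16 periportal genes, a gap of 1.77 with a 95% interval of 0.94 to 2.59. On these 2 arrays this argues against hepatocyte dilution as the whole cause, and a partial contribution stays open. The list medians had been seen when the comparison was chosen, so it is no independent test. Globule-containing areas nearer the central veins are another candidate explanation, which the pericentral median of 0.40 does not decide, with an interval of -0.36 to 0.88 over members that went both ways. An effect of the globules themselves cannot be told apart from lobular position, since the areas were chosen by globule content alone.

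The higher stellate list could reflect more of every non-parenchymal cell type in the capture. Endothelial markers, which would then be higher by a like amount, had a median 1.68 below that of stellate markers, with an interval of 1.06 to 2.53. On these 2 arrays this argues against a like increase of every cell type. The list medians had been seen when the comparison was chosen, so it is no independent test. More stellate cells or fibroblasts in the globule-containing areas, and higher expression per cell, both stay open and were not tested.

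The lower male-biased genes could reflect a different mix of sexes in the pools. The 3 measured Y-linked genes, Eif2s3y, Kdm5d and Uty, differed by a median of 0.11, between 0.09 and 0.51, and Xist lay below background on both arrays, so a different mix of sexes is argued against. Fewer hepatocytes in the capture were not tested for these genes and stay open. A loss of sex-biased expression in hepatocytes with globules is a hypothesis that these 2 arrays cannot separate from differences between areas.

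A hypothesis from the split of macrophage markers is that macrophages of a lipid-associated kind stand in place of resident Kupffer cells in globule-containing areas. In a second list, 16 of 21 lipid-associated macrophage genes above the floor were at least 2-fold higher, with a median of 1.64. Among them were Mmp12, a macrophage elastase, at a log2 difference of 4.53 and Cd63 at 4.23. Cstb had a log2 signal of 16.69 against 12.77. Mmp12, Cd63 and Cstb were chosen after their values were seen. A second list of 12 resident Kupffer genes had a median of 0.09 with an interval of -0.37 to 0.46. The gap of 1.55 had an interval of 0.80 to 2.57. Above the floor, 1 member of each list was also in a fixed list, Plin2 and Hmox1, and without them the medians were 1.77 and 0.02. The gap met the prediction written for it, but the lower signal of the resident markers did not recur in the second list. That list is a weak test of a loss of these cells. Hmox1 is also in the NRF2 list, which was higher, and Cd163, Kcna2, Xcr1 and Slc16a9 lay below the floor. Whether replacement is the right description stays undecided, since the resident interval ran from -0.37 to 0.46. Trem2 and Ctsk of the lipid-associated list, chosen after their values were seen, lay near background, at 5.30 against 4.68 and 5.05 against 4.57. Several lipid-associated genes, such as Plin2 and Cd36, are also expressed by hepatocytes. Which cells carry the genes of this list was not measured.

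A further hypothesis is that NRF2 targets in general were higher. A second list of 21 targets had a median of 0.56 with an interval of 0.16 to 1.68 at percentile 99.7, which is consistent with it, and 9 of 21 were at least 2-fold higher. Among them, chosen after their values were seen, were Gstm2 at 3.59, Gstm4 at 2.95 and Gsr, glutathione reductase, at 2.09 on the log2 scale. The Gstm genes can share hybridisation. The areas differ in cell types as well, and which cells carry the NRF2 targets was not measured.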
